A study of Caenorhabditis elegans with 2 samples.

How the data were processed

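ChIP-seq was carried out against an eGFP fusion of ZIP-8, a bZIP transcription factor of Caenorhabditis elegans, in mixed-stage embryos. Per the labels, 2 biological replicates of whole organisms were sequenced, each from a biosample of its own, and both belong to 1 group. The labels do not say whether the biosamples were grown as separate cultures, so the spread between them may be partly technical.

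The authors deposited lists of peaks in narrowPeak format on the genome builds ce11 and ce10. Per the file headers, each replicate has an unthresholded ranked list made from its own alignments and a control file, and a pooled list was made in the same way from the alignments of both replicates. The optimal list was derived from those lists with the irreproducible discovery rate (IDR), a measure of how well ranks are shared between replicates, per the file headers. The aligner, the peak caller, the filters and the IDR threshold are not given in the sources used here. The optimal list on ce11 was identical to the 2634 peaks of highest signal in the pooled list, so it rests on pooled reads and is not independent of either replicate.

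The signal of each peak is the deposited enrichment value of the authors' caller, whose scale is not given in the sources used here. It is the authors' value and was used to describe, rank or filter peaks within a list and, between the replicate lists, only for a rank correlation. The deposited significance column holds −log10 of a q-value as the authors' caller gave it, and it was constant at 4.09 over the optimal list, so it was not used for ranking. The column for −log10 of a p-value was empty and was not used here. Summits were taken from the offsets in the deposited lists. Read counts per library are not given in the lists, so the sequencing depth is unknown. The control, the alignments and the signal tracks were not analysed here.

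Peaks on ce11 were compared with the Ensembl release 115 annotation and the genome sequence of the same coordinates, and the last peak end of each chromosome lay within the chromosome's length. Coordinates are 1-based and on ce11 throughout, and none was converted between builds. Unless stated otherwise, results refer to the 2610 optimal peaks on the 6 nuclear chromosomes. A promoter summit lay from 1000 bp upstream to 200 bp downstream of the start of an annotated protein-coding transcript. Other summits were assigned to an exon, then an intron, then intergenic sequence, in that order. A gene was called bound when an optimal summit lay in the same window around one of its transcript starts.

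The tests, the alternatives to them, the 41 gene lists, the 16 motifs and the rule for named genes were fixed before the data were examined. By that rule the text names the 25 optimal peaks of highest signal with their promoter or nearest gene, zip-8 and unc-119, all bound bZIP genes, and the 4 bound members of highest signal in each gene list that passed the test. Other named genes are said to have been chosen after their values were seen.

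Replicate lists were compared with the optimal list by overlap of at least 1 bp, against 1000 circular shifts of the optimal peaks along each chromosome. The resulting permutation p-values are one-sided, and the smallest possible value is 0.000999. Those of circular shifts over gene lists are two-sided, and the lowest found there was 0.001998. Chromosome counts were compared with chromosome length by exact two-sided binomial tests and with the lower-ranked peaks of the pooled list by Fisher's exact test. Promoter summits were compared with the same kind of shifts and with the lower-ranked peaks. Each gene list was compared with all other genes of its kind (protein-coding genes for lists of protein-coding genes, all genes for lists of noncoding genes and pseudogenes) by two-sided Fisher's exact tests. Motifs were counted within 50 bp of each summit and in a window of the same width centred 250 bp to the side, alternately left and right, and compared by exact two-sided McNemar tests. Words of 6 bases were ranked on chromosomes I, III and V, and the 20 best were tested on II, IV and X. All adjusted p-values are Benjamini-Hochberg values within each family of tests. Intervals are exact Clopper-Pearson 95% intervals, or for ratios of bound shares 95% intervals on the log scale, and cover counting error only. Peaks and genes near each other are not independent, and tests over peaks describe this set of peaks, not a population of animals.

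After the motif results were seen, a full bZIP site was defined as a match to any of 5 patterns of 8 bases, TGACGTMA, TTGCGCAA, TTACGTAA, TGATGCAA and TGACGCAA, with M standing for A or C, within 50 bp of the summit. Results that use this definition were chosen after the data had been seen. Of the 16 motifs, TTRCNNYAA was listed for C/EBP sites with a free centre but has 9 bases, so it cannot match the C/EBP palindrome of 8, and it was kept as fixed.

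The procedures were tested on simulated data. With 19973 genes and 6 lists planted among 34, lists bound 2, 3 and 4 times as often as other genes were recovered in 16.0%, 69.0% and 93.3% of cases over 50 simulations, and at most 0.8% of unplanted lists were called. The planted lists were larger than those of 30 bZIP and 14 mitochondrial stress genes, so recovery of such short lists was not measured. Genes were drawn independently, so false calls from neighbouring genes that share a peak were not simulated. For 2610 windows, a motif planted in 1% of them was recovered in 40.0% of 20 simulations, and one planted in 2% or 10% in 100.0%. With 99 circular shifts, unmoved random summits were called enriched in promoters in 7% of 100 simulations, and sets with 10% of summits moved into promoters in 100%.

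The alternatives tried were the ce10 lists, other definitions of a shared peak, the 50% of optimal peaks with the higher signal, promoter windows of 500 and 2000 bp, motif windows of 25 and 100 bp, shuffled sequence as the reference for motifs, genes with any pooled peak as the background, circular shifts as the test for gene lists, and the top peaks of each replicate alone. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.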

Results

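Binding of ZIP-8 was profiled in C. elegans embryos of mixed stages that carry an integrated transgene for ZIP-8 fused to enhanced GFP. The data comprised 2 biological replicates of whole organisms in 1 group, and the comparisons made here ask where in the genome the tagged factor was found and what sequence and genes lay at its peaks. No untagged strain, input or other condition was analysed, so no difference between conditions could be tested. On ce11 the list of replicate 1 held 22803 peaks, that of replicate 2 held 12222 and the pooled list held 30000. The optimal list held 2634 peaks, 2610 on nuclear chromosomes and 24 on the mitochondrial genome. Its median width was 290 bp and its median signal 38.5 (interquartile range 27.6 to 59.2), with a lowest signal of 21.4 and a highest of 1224. The number of reads behind these lists is unknown.

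The highest signals lay over egl-5, the Hox gene of the Abdominal-B type that patterns the posterior body. An interval of 2655 bp at III:7814335–7816989 covered most of the gene (III:7814374–7817141) and held 5 summits, of which 4 ranked 1 to 4 in the list with signals of 1224, 1039.6, 591 and 577. The summit of rank 1 lay in the last exon, and those of ranks 2 to 4 lay in introns. The remaining summit of the interval, at rank 30, had a signal of 239 and was exonic. In the separate lists, the interval held the peak of rank 1 in replicate 1 (signal 543) and in replicate 2 (signal 666). The next widest interval of the optimal list measured 753 bp. None of the 5 summits had a full bZIP site within 50 bp.

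**Figure D1:**
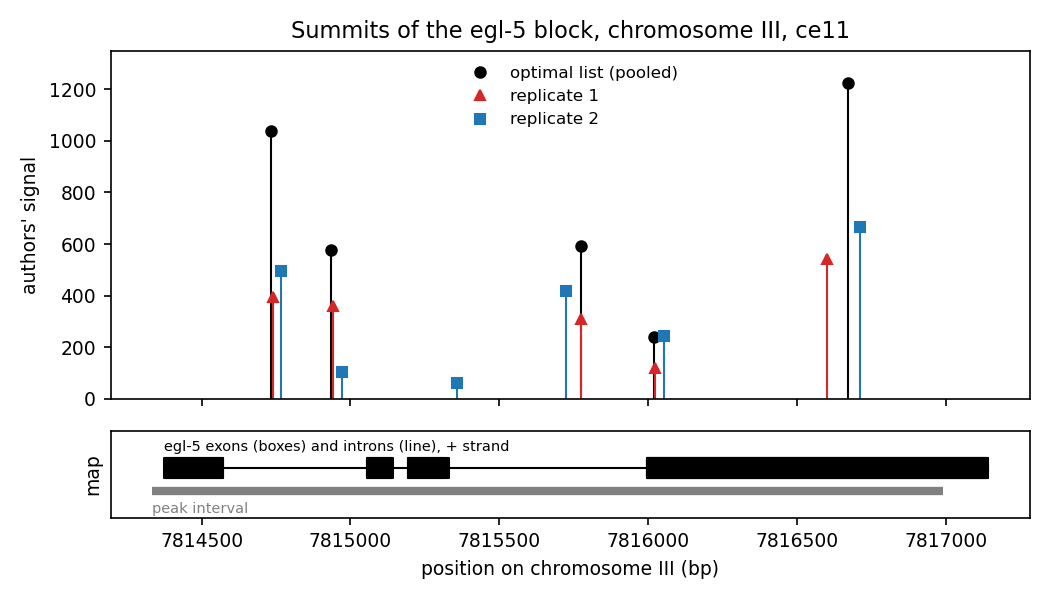
Summits over egl-5 on chromosome III of ce11, with position in bp on the horizontal axis and the authors' signal on the vertical axis of the upper panel, for the optimal list and for each replicate. The lower panel shows the exons, the introns and the peak interval of 2655 bp. The summit of the optimal list with a signal of 1224 stands over the last exon, and 3 of its 5 summits stand over introns.

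Outside egl-5, the strongest peaks lay at genes of varied kinds, and 20 of the 21 others among the 25 highest held a full bZIP site. The CRE palindrome TGACGTCA, the site of the CREB and ATF families, was found at 14 of them. It lay 15 bp from the summit at the promoter of lido-8 (II:2998052, signal 524), and 10 bp from a summit in an intron of hmr-1, the classical cadherin gene (I:11102512, signal 475). Further CRE palindromes lay at a summit in an exon of tcc-1, with the chemoreceptor gene srh-286 as the nearest start (V:17845835, signal 369), and in an intron of the scramblase gene scrm-6 (I:11254529, signal 359). The intergenic summits nearest hecw-1, scrm-8 and F29B9.12 had signals of 357, 327 and 319 and also held the CRE palindrome. The same sequence was present in introns of T23B5.3, ptr-18, W10C8.6 and daf-2, the insulin receptor gene (III:3019022, signal 266). It was also found at the promoters of abt-2 and C25F9.2 and in an exon of Y43D4A.5, with signals of 282, 276 and 247.

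The C/EBP palindrome TTGCGCAA was found at 4 of these 21 peaks. They were the promoter shared by Y51F10.11 and spe-48 (I:1958560, signal 307), the promoter of the acyl-CoA dehydrogenase gene acdh-6 (III:8560598, signal 303), the promoter of T24E12.2 (II:3782509, signal 300.03), and the intergenic summit nearest the collagen gene col-61 (I:7199022, signal 253). TGACGTAA lay near the summit closest to C47G2.3 and TTACGTCA near a summit in an intron of Y62F5A.9 with Y62F5A.12 as the nearest start, with signals of 268 and 249. The promoter peak of F54E7.6 (III:5661140, signal 285) had no full site. By location, the 25 peaks comprised 7 in promoters, 3 in exons, 10 in introns and 5 in intergenic sequence.

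Sequences of the bZIP class marked the summits of the whole list. The CRE palindrome was found within 50 bp of 1030 of 2610 summits (39.5%, 95% interval 37.6 to 41.4) and in 1.23% of side windows, a ratio of 32.2 (exact McNemar test, two-sided, adjusted p = 7.05e-284). The C/EBP palindrome occurred at 16.3% of summits and in 0.498% of side windows (ratio 32.8, adjusted exact p = 2.12e-110). The hybrid of the C/EBP and CRE patterns, TGACGCAA, occurred at 9.46% against 0.192% (ratio 49.4, adjusted exact p = 7.34e-66), and the PAR palindrome TTACGTAA at 3.45% against 0.115% (ratio 30, adjusted p = 7.22e-23). TGATGCAA, the composite site of C/EBP and ATF factors, was less common, at 1.84% against 0.230% (ratio 8.0, adjusted exact p = 5.79e-09). The XBP-1 pattern TGACGTGK (K for G or T) stood at 2.76% against 0.651% (ratio 4.24, adjusted exact p = 5.79e-09), and the SKN-1 pattern RTCAT (R for A or G) at 64.7% against 32.3% (ratio 2.00, adjusted p = 1.30e-111). GTCAT, a match to the SKN-1 pattern, lies inside ATGACGTCAT, so SKN-1 and CRE counts overlap. The ratios moved when a replicate was left out, to 14.5 without replicate 1 and 20.8 without replicate 2 for the hybrid, and to 18.3 and 101 for the PAR palindrome. These ratios rest on few side windows with a match, 11 and 12 for the hybrid and 3 and 1 for the PAR palindrome. Without replicate 1 the shares at summits were 23.2% for the CRE palindrome, 11.03% for the C/EBP palindrome, 6.09% for the hybrid, 2.11% for the PAR palindrome and 1.69% for XBP-1.

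The AP-1 site TGASTCA (S for C or G), which differs from the CRE by a missing central base, was not detectably different at summits and to the side (0.728% and 0.690%, ratio 1.06, adjusted exact p = 1.0). Nor did the E-box CACGTG (ratio 1.29, adjusted exact p = 0.275), the GAGA repeat (ratio 1.13, adjusted p = 0.827), the SP1-like GC box CCGCCC (ratio 1.21, adjusted p = 0.388) or TTRCNNYAA (ratio 0.941, adjusted p = 0.725) pass the test. TTRCNNYAA was listed for C/EBP sites but has 9 bases and cannot match the palindrome of 8, so its counts do not bear on such sites. The GC box passed it among the top peaks of replicate 2 alone, without replicate 1 (ratio 1.48, adjusted exact p = 0.0235). GATA sites, the trans-splice acceptor TTTTCAG and runs of 8 T were less frequent at summits than to the side, at 15.8% against 19.4% (ratio 0.814, adjusted exact p = 0.00110), 6.44% against 10.9% (ratio 0.589, adjusted p = 8.70e-09) and 6.82% against 14.2% (ratio 0.480, adjusted p = 1.32e-18). Against shuffled sequence the last 2 of these turned over, to ratios of 2.55 and 1.41. By the same reference the GC box (ratio 2.96, adjusted exact p = 1.31e-06) and the GAGA repeat (4.33, adjusted p = 0.000262) were more frequent at summits, and TTRCNNYAA (0.696, adjusted p = 0.000693) and AP-1 (0.528, adjusted p = 0.0320) less frequent. The E-box passed the test within 100 bp (ratio 1.36, adjusted exact p = 0.0224). Mean GC content was 38.5% ± 8.05 (SD over windows) at summits and 35.2% ± 8.56 to the side.

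**Figure D2:**
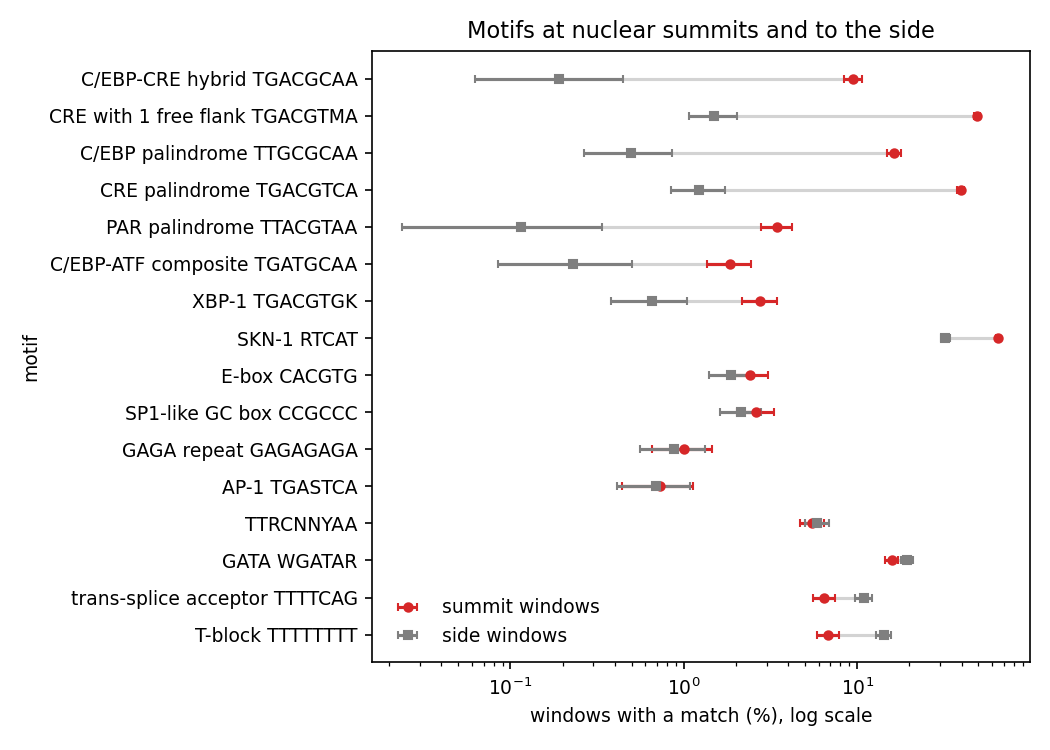
Share of windows with each of 16 motifs at the 2610 nuclear summits (circles) and in side windows centred 250 bp away (squares), in percent on a log axis, with exact 95% intervals. The CRE palindrome stands at 39.5% of summits and 1.23% of side windows, while AP-1 stands at 0.728% and 0.690%.

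A search without chosen motifs returned pieces of the same sites. Of 2080 words of 6 bases ranked on 3 chromosomes, the 20 best were each more frequent at summits on the other 3 chromosomes. The best was ACGTCA, found at 49.8% of 1172 summits and in 3.84% of side windows (ratio 12.98, adjusted exact p = 2.31e-133), followed by GACGTC (37.9% against 1.62%) and ATGACG (47.2% against 2.73%), all parts of the CRE with its flanking bases. The next word in rank, CGTCAC, has C rather than T after the CRE and stood at 30.5% against 1.88%. ATTGCG (29.4% against 2.90%) and CGCAAC (23.6% against 2.22%) are parts of C/EBP sites. With shuffled sequence as the reference, 20 words were again more frequent, and 19 were shared between the lists.

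A full bZIP site lay within 50 bp of 2052 of the 2610 summits (78.6%, 95% interval 77.0 to 80.2), of 2.45% of side windows and of 8.83% of the 27362 lower-ranked summits. The share was 86% among ranks 1 to 100, 77.9% among ranks 1001 to 2000, 69.7% among ranks 2001 to 2610 and 43.6% among ranks 2611 to 5000. Within the top 100 the CRE palindrome was found at 62% of summits and the C/EBP palindrome at 13%, among ranks 501 to 1000 at 34.8% and 25%, among ranks 1001 to 2000 at 40.9% and 13.8%, and among ranks 2001 to 2610 at 38.5% and 8.52%. Among peaks with the palindrome within 100 bp, the median distance to the summit was 14 bp for the CRE (1100 peaks) and for C/EBP (475 peaks). The median signal was 50.2 at 419 peaks with the C/EBP palindrome and no CRE (TGACGTMA), 37.6 at 1272 peaks with a CRE and no C/EBP palindrome, 167.2 at the 7 peaks with both, and 32.1 at 558 peaks with no full site. The top 2610 peaks of replicate 1 held a full site in 79.96% of cases and those of replicate 2 in 48.9%. These are 2 single libraries whose lists overlap, so no p-value is given for the difference.

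**Figure D3:**
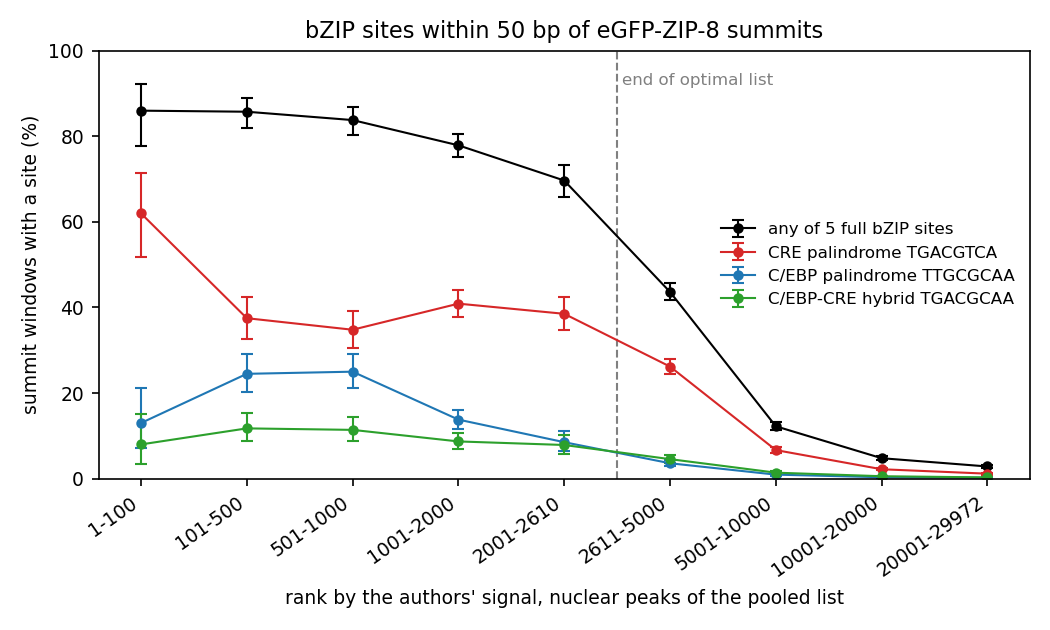
Share of summit windows with a bZIP site, in percent with exact 95% intervals, by rank of the authors' signal among nuclear peaks of the pooled list. The black line, for any of the 5 full sites, falls from 86% at ranks 1 to 100 to 2.85% at ranks 20001 to 29972, and the dashed line marks the end of the optimal list.

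Summits lay in the promoter windows of 873 of 19973 protein-coding genes (4.37%), against a mean of 731 over shifted positions (range 644 to 807). Of the 41 gene lists, 6 were bound more often and 3 less often than other genes. Genes of the mitochondrial stress response were bound at 4 of 14 (ratio 6.56, Fisher's exact test, adjusted p = 0.0174). These were ubl-5 and dve-1, regulators of the mitochondrial unfolded protein response, the prohibitin gene phb-1 and the mitochondrial protease gene clpp-1, with signals of 63.1, 21.5, 36.3 and 25.02. All 4 had a full site, the C/EBP palindrome at ubl-5 (I:5608954–5608961), phb-1 (I:2070955–2070962) and dve-1 (X:433343–433350), and the CRE palindrome at clpp-1 (II:10302804–10302811). Over 8 alternatives the ratio of this list ranged from 2.77 to 10.6 and its adjusted p, from exact or permutation tests, from 0.00899 to 0.759, and among the top peaks without replicate 1 the ratio was 4.36 (adjusted p = 0.0787).

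Homeodomain genes were bound at 15 of 95 (ratio 3.66, Fisher's exact test, adjusted p = 0.000155). The members of highest signal were ceh-16, the engrailed gene of the worm (III:8622182, signal 102), eyg-1 (II:9828631, 56.4), unc-42, a regulator of neuronal identity (V:9765256, 54.6), and pal-1, the caudal gene (III:4809928, 43.9), and of these eyg-1 had a full site, the C/EBP palindrome. Bound bZIP genes numbered 5 of 30 (ratio 3.83, Fisher's exact test, adjusted p = 0.0412). They were zip-8 itself (signal 182), zip-7 (IV:16506001, 86.8), the immune regulator atf-7 (III:4494357, 35.2), the infection response gene zip-2 (III:833892, 31.3) and xbp-1 (III:4193821, 23.4), a factor of the unfolded protein response of the endoplasmic reticulum, with a full site at zip-8 and atf-7. The transgene also carries zip-8, and the bZIP list was not tested without it. Of 8 alternatives each, the call ended in 2 for homeodomain genes and 4 for bZIP genes. The homeodomain ratio was then 1.92 for the 50% of peaks with the higher signal (adjusted exact p = 0.687) and 1.72 without replicate 1 (adjusted p = 0.296). The bZIP ratio was 3.04 for the peaks with the higher signal (adjusted exact p = 0.687), 1.80 among genes with any pooled peak (adjusted p = 0.554), 1.95 over peaks with a full site (adjusted p = 0.663) and 2.59 with circular shifts (adjusted permutation p = 0.364). With promoters of 500 bp the bZIP ratio was 6.17 (adjusted exact p = 0.0163).

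Histone genes were bound at 9 of 81 (ratio 2.56, Fisher's exact test, adjusted p = 0.0412). Among them were his-1 (V:16041612, signal 113) with a CRE palindrome, the linker histone gene hil-4 (V:4753349, 51.7) with a C/EBP palindrome, and the neighbours his-67 and his-68, which shared a peak without a full site (I:9988915, 30.01). Of the genes of the cell cycle and DNA replication, 10 of 87 were bound (ratio 2.65, adjusted exact p = 0.0270), led by sld-5 of the GINS complex (V:20235431, 125), the phosphatase gene cdc-25.2 (V:1576883, 73.6), the cyclin A gene cya-1 (III:9109950, 66.5) and the helicase gene mcm-2 (II:12006937, 51.4). Genes for small nucleolar RNAs were bound at 30 of 346 (ratio 2.44, adjusted exact p = 0.000155), with the highest signals at T24H10.12 (II:9125758, 123), F56A11.14 (IV:563259, 86.001), T02E1.9 (I:8224420, 79.1) and C05H8.3 (III:5654749, 77.1). Some small nucleolar RNA genes shared a peak with each other or with a protein-coding gene such as phb-1, so these calls are not independent. Their background of all genes includes the piRNA genes, of which 2.32% were bound. Of 8 alternatives each, the call ended in 7 for histones, 6 for the cell cycle and 3 for small nucleolar RNAs, and the adjusted p from exact or permutation tests reached 0.955, 0.439 and 0.439. The lowest ratios were 1.12, 1.73 and 1.62. Some calls ended at higher ratios than the main ones. With circular shifts the ratio to the shifted mean was 3.58 for histones (adjusted permutation p = 0.0614) and 2.84 for the cell cycle (adjusted p = 0.0683). For the cell cycle the value of 0.439 came at a ratio of 2.63, for the 50% of peaks with the higher signal. Without replicate 2 the histone ratio was 1.45 (adjusted exact p = 0.861) and the cell cycle ratio 2.44 (adjusted p = 0.0605).

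Chemoreceptor genes were bound at 38 of 1364 (ratio 0.621, Fisher's exact test, adjusted p = 0.0174), piRNA genes at 356 of 15363 (ratio 0.550, adjusted p = 2.72e-25) and pseudogenes at 42 of 2128 (ratio 0.538, adjusted p = 0.000155). Bound chemoreceptor genes of highest signal were srd-43 (X:13305979, 95.005), srt-6 (V:7408720, 92.5), srt-4 (V:2577391, 78.7) and srw-7 (V:3805654, 69.2), each with a full site. The piRNA genes 21ur-3718 and 21ur-6749 shared a peak of signal 156 at IV:16389031, and 21ur-13846 (IV:3661317) and 21ur-770 (IV:16391672) had signals of 114 and 94.9. Among pseudogenes the highest signals were 327, 202, 123 and 75.2, at WBGene00019529, WBGene00023234, WBGene00012077 and WBGene00023243. How far these classes lie in clusters was not measured. When summits were shifted along the chromosomes, the adjusted permutation p was 1.0 for chemoreceptors, 0.686 for piRNA genes and 0.0655 for pseudogenes. The ratios in that test were 0.918, 0.867 and 0.664. Among genes with any pooled peak in the promoter the calls also ended for chemoreceptors (ratio 0.955, adjusted exact p = 1.0) and pseudogenes (0.810, adjusted p = 0.554), and piRNA genes stood at 0.670 (adjusted p = 1.24e-11). Chemoreceptors did not pass for the 50% of peaks with the higher signal (0.651, adjusted exact p = 0.456). The lowest ratios were reached without replicate 1, at 0.341, 0.356 and 0.458 (adjusted exact p = 6.32e-09, 1.39e-69 and 4.39e-07).

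The remaining 32 lists did not pass the test. Genes of endoplasmic reticulum stress stood at 4 of 22 (ratio 4.17, Fisher's exact test, adjusted p = 0.0580), cytosolic ribosomal proteins at 6 of 80 (ratio 1.72, adjusted p = 0.376) and nuclear hormone receptors at 12 of 274 (ratio 1.00, adjusted p = 1.0). No bound gene was found among 66 mitochondrial ribosomal proteins, 45 intestinal, 28 pan-neuronal and 6 vitellogenin genes. Ribosomal proteins passed the test without replicate 1 (ratio 2.56, adjusted exact p = 0.0215) and stood at 0.585 without replicate 2 (adjusted p = 1.0), and endoplasmic reticulum stress stood at 2.78 and 2.13 (adjusted p = 0.205 and 0.678). Without replicate 1, genes of heat shock, splicing, translation factors, transfer RNAs and microRNAs also passed as bound more often, and innate immunity effectors as bound less often (ratio 0.442, adjusted exact p = 0.0399). Among protein-coding genes with any pooled peak in the promoter, 1 list was still bound more often, the homeodomain genes (ratio 2.83, adjusted exact p = 0.00293). With circular shifts 2 were, homeodomain and small nucleolar RNA genes (adjusted permutation p = 0.0410 each). Both had an unadjusted two-sided permutation p of 0.001998, the lowest among the lists.

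**Figure D4:**
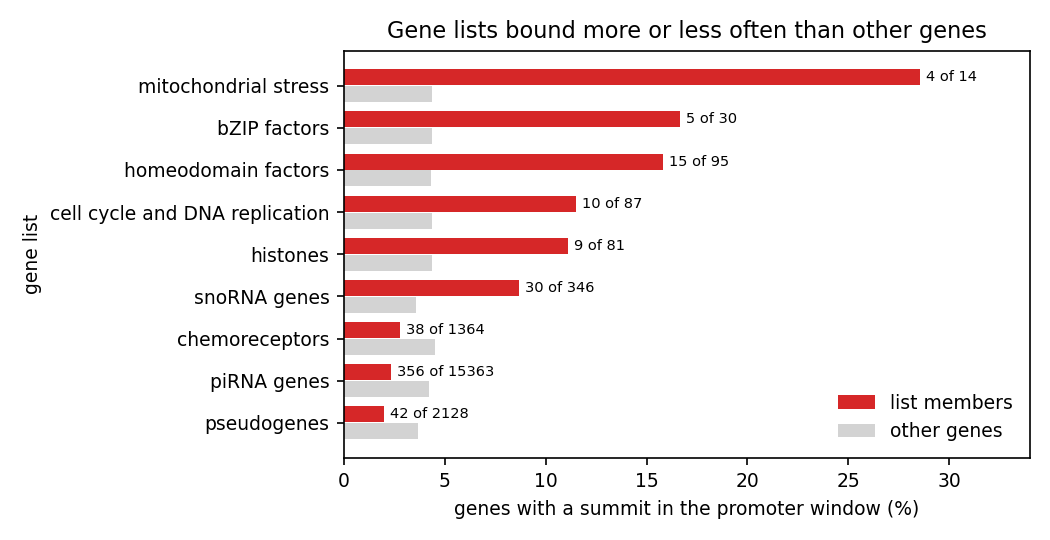
Percentage of genes with an optimal summit in the promoter window for the 9 lists that passed the test, with list members in red and all other genes of the same kind in grey, and counts beside the bars. Genes of the mitochondrial stress response stand at 4 of 14 and pseudogenes at 42 of 2128.

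Peaks at zip-8, which the transgene also carries, and at unc-119, which is mutant in the strain, were examined separately. At zip-8 (III:6478955–6481243), 4 optimal peaks lay within 20 kb, where 1.35 would follow from the density of chromosome III, while 1 lay within 20 kb of unc-119, where 1.48 would follow. The strongest, at III:6478836 with a signal of 182 and rank 61, lay in the zip-8 promoter 11 bp from the PAR palindrome TTACGTAA. A further promoter summit at III:6478456 (signal 154, rank 93) and an upstream summit at III:6477357 (signal 76.2, rank 390) had no full site. Within unc-119 (III:10902641–10908935), an intronic summit at III:10903187 had a signal of 138 and rank 123, with the CRE palindrome at III:10903207–10903214.

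Summits fell in promoters at 812 of 2610 (31.1%, 95% interval 29.3 to 32.9), against 26.1% at shifted positions, a ratio of 1.19 (one-sided permutation p = 0.000999, the smallest possible). Lower-ranked peaks fell there at 29.6%, which was not detectably different (Fisher's exact test, two-sided, p = 0.0971), although without replicate 1 the share was 33.9% (p = 3.62e-06). Exons held 399 summits (15.3%), fewer than the 21.8% of shifted positions (one-sided permutation p = 0.000999), and the rest lay in introns (733, 28.1%) and between genes (666, 25.5%). The median distance from a summit to the nearest start was 1244.5 bp, and 1206 bp for lower-ranked peaks. Summits with a full site lay in exons at 17.4% and those without at 7.35% (Fisher's exact test, two-sided, adjusted p = 1.89e-09), while their shares in promoters were 30.8% and 32.4% (adjusted p = 0.470) and those between genes 24.1% and 30.8% (adjusted p = 0.00295).

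Chromosomes I and III carried more peaks than their length would give. Chromosome I held 488 (ratio 1.24, exact binomial test, adjusted p = 2.34e-06) and III held 440 (ratio 1.23, adjusted p = 2.08e-05), whereas IV held 391 (ratio 0.859, adjusted p = 0.00159) and X held 416 (ratio 0.902, adjusted p = 0.0313). Chromosomes II and V did not pass the test, with ratios of 0.918 and 0.936 (adjusted exact p = 0.0920 and 0.0966). Against the lower-ranked peaks, I stood higher (18.7% against 16.5%, Fisher's exact test, adjusted p = 0.0153) and IV and X lower (14.98% against 16.8%, adjusted p = 0.0386, and 15.9% against 18.2%, adjusted p = 0.0153), and III did not differ detectably (adjusted p = 0.0819). Without replicate 1 the ratio of X was 0.997 (adjusted exact p = 0.980) and that of V was 0.793 (adjusted p = 8.73e-08). Chromosome IV did not pass the test for the 50% of peaks with the higher signal (ratio 0.887, adjusted exact p = 0.0942) or over peaks with a full site (ratio 0.905, adjusted p = 0.0719).

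Of the 2610 optimal peaks, 2587 (99.1%) overlapped a peak of replicate 1 and 2134 (81.8%) a peak of replicate 2. Both replicates covered 2113 (81.0%, 95% interval 79.4 to 82.4), against 2.16% of shifted peaks. The optimal list was taken from the pooled reads of both replicates with a threshold on shared ranks, so this overlap follows in part from how the list was made and is no independent test. Across these 2113 peaks, which are not independent replicates, Spearman's rho between the signals of the replicates was 0.351. These peaks were selected by high pooled signal and by presence in both lists, so rho covers a restricted range of signals. Of the 500 strongest nuclear peaks of replicate 2, 98.0% overlapped the list of replicate 1, and 91.8% of the 500 strongest of replicate 1 overlapped that of replicate 2. The lists of the 500 strongest peaks had 236 (47.2%) in common.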

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

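The set of sequences counted as a full bZIP site, and the test of binding at a full site in each window, were chosen after the results were seen, and the remaining test of this part before its result was seen.

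The mitochondrial genome, which lies outside the nuclear comparisons, carried 24 peaks of the optimal list, and no control sample was analysed. They covered 44.01% of its 13794 bp, with a median signal of 69.5 and a highest of 208.8 at rank 42. The lists of replicates 1 and 2 held 30 and 32 mitochondrial peaks. None of the 24 summit windows held a full bZIP site (0%, 95% interval 0 to 14.2), against 78.6% of nuclear summits, and the whole mitochondrial genome holds 1 such site. The 24 windows do not overlap, so 1 site in the genome argues against binding at a full site in each window. Wherever the summits lay, at most 1 window could have held it, so the share of 0.0% does not test the other explanations. Both mitochondrial DNA of high copy number read without binding at a full bZIP site and binding that needs no full site stay open as a candidate source. The lists were made with a control file, per the file headers, and how far it removes the effect of copy number was not tested. The copy number itself was not measured, and no biological explanation was tested in this design of 1 group.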

How the results depend on the processing

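The alternatives that use only peaks with a full bZIP site, and the merging of overlapping intervals, were chosen after seeing the data. Of 52 alternative values for the main results, 41 stayed within their limits and 11 moved. The share of optimal peaks found in both replicates was 63.0% with 50% reciprocal overlap, 75.4% with summits within 100 bp, 90.8% for the 50% of peaks with the higher signal and 82.8% on ce10. Lists bound more often numbered 1 among genes with any pooled peak, 0 for the 50% of peaks with the higher signal, 2 with circular shifts, 2 with site peaks alone, and 4 to 10 when a replicate was left out, with 10 without replicate 1. Lists bound less often numbered 1 among genes with any pooled peak and 0 with circular shifts. Fewer genes or peaks were tested in some of these settings, and otherwise the cause was not tested. The ratio of promoter summits to shifted positions stayed between 1.11 and 1.31 over 6 alternatives, motifs more frequent at summits numbered 8 to 12, and the ratio of the CRE palindrome stayed between 16.2 and 129.

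Among 198 alternative values for single lists, motifs and chromosomes, 148 kept their direction and side of the threshold, 35 no longer passed it, 6 newly passed it and 9 did not keep their direction, among them AP-1 within 25 bp, which had none there. The ratio of AP-1 was 1.00 within 25 bp, 0.528 against shuffled windows and 0.880 to 1.11 when a replicate was left out, with the lower value without replicate 2. TTRCNNYAA stood at 1.05 within 100 bp and 0.974 to 1.03 when a replicate was left out, the E-box at 0.903 for the 50% of peaks with the higher signal and the GAGA repeat at 0.533 within 25 bp. Against shuffled windows the trans-splice acceptor stood at 2.55 and the T-block at 1.41. The cause was not tested. The number of reads is unknown, so what depth limits could not be measured.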

Other observations

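The tests and counts of this part were chosen after the data were seen, except 2 tests that were chosen before their results were seen, those of extra egl-5 DNA and of full sites in the gene lists together.

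Many copies of the bZIP sites in the genome were not near an optimal summit, and the share near one differed with the bases beside the site. Of 6026 CRE palindromes on the nuclear chromosomes, 1158 (19.2%, 95% interval 18.2 to 20.2) lay within 50 bp of an optimal summit, as did 441 of 1591 C/EBP palindromes (27.7%) and 51 of 4578 copies of TGATGCAA (1.11%). The shares within 50 bp of any summit of the pooled list were higher, at 41.7%, 39.8% and 7.71%. The counts that follow refer to optimal summits. With A before and T after the palindrome, ATGACGTCAT was near a summit at 445 of 766 copies (58.1%), against 7.31% of 3080 copies with neither base (ratio 7.95, Fisher's exact test, two-sided, p = 1.41e-198). ATTGCGCAAT was near a summit at 79 of 120 copies (65.8%), against 9.04% of 741 (ratio 7.28, exact p = 9.53e-41). CRE palindromes were near a summit at 22.8% in promoters, 15.8% in introns and 22.4% in exons, the last against 18.3% elsewhere (Fisher's exact test, adjusted p = 0.00218). C/EBP palindromes in exons stood lower, at 12.7% against 29.5% elsewhere (adjusted exact p = 7.27e-06).

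Several gene lists stood out over the 558 peaks without a full site. Cytosolic ribosomal protein genes were bound at 6, namely rpl-12, rps-19, rps-1, rpl-3, rpl-35 and ubl-1, with signals of 40.2, 29.4, 26.3, 23.3, 21.8 and 21.7, and 0 of them had a full site, against 79.0% of other bound protein-coding genes (Fisher's exact test, two-sided, p = 9.36e-05). The signals of rpl-35 and ubl-1 lie close to the lowest of the optimal list, 21.4. With and without a site together, the ratio of this list was 2.56 among the top peaks without replicate 1 and 0.585 without replicate 2. Over peaks without a site the ratio of this list was 8.20 (adjusted exact p = 0.00148). Genes of endoplasmic reticulum stress reached a ratio of 14.7 over the same peaks (adjusted exact p = 0.00908), with the chaperone genes hsp-3 and crt-1 and the factor xbp-1 bound without a full site, and the kinase gene pek-1 with TTGCATCA. Genes for transfer RNAs reached 2.56 (adjusted exact p = 0.0181), for small nucleolar RNAs 5.34 (adjusted p = 1.55e-05), for histones 6.71 (adjusted p = 0.00908), for homeodomain factors 5.72 (adjusted p = 0.0140) and for bZIP factors 10.8 (adjusted p = 0.0162). The signals were 33.6 at hsp-3, 26.8 at crt-1, 23.4 at xbp-1 and 37.8 at pek-1. These genes were named after their values were seen. The patterns of a full site leave out the XBP-1 pattern TGACGTGK, whose matches were not counted for these lists.

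The peaks over egl-5 stood apart in width and signal from the rest of the list. Spliced egl-5 RNA or cDNA in the libraries would hold no intron sequence, and 3 of the 5 summits lay in introns. In the separate lists, 3 lay there in replicate 1 and 4 in replicate 2. The 3 of the optimal list lay 162, 121 and 222 bp from an exon. These distances are shorter than the median peak width of 290 bp. Summit positions alone therefore cannot separate reads of exons from reads of introns, and this explanation stays open. Binding at a full bZIP site in each summit window is argued against by the sequence, since the interval of 2655 bp held 1 full site, outside the 5 windows, which do not overlap. The summits lie in 1 interval and count as 1 locus, so no p-value is given. Extra egl-5 DNA in the libraries without binding is a candidate explanation that stays open, as does binding that needs no full site. With 1 site in the interval at most 1 window could have held it, so 0 of 5 windows with a full bZIP site does not test extra egl-5 DNA. The lists were made with a control file, per the file headers, and whether the control also held extra egl-5 DNA is unknown. No biological explanation was tested beyond these.

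Of the bound members of the 6 gene lists bound more often, 43 of 73 had a full site in a promoter peak (58.9%), against 1275 of 1612 other bound genes (79.1%, Fisher's exact test, two-sided, p = 0.000131). Taken singly, small nucleolar RNA genes had a site at 16 of 30 (unadjusted exact p = 0.00255) and histone genes at 4 of 9 (p = 0.0260). Homeodomain, bZIP, cell cycle and mitochondrial stress genes did not differ detectably from other bound genes (unadjusted exact p from 0.0698 to 0.583). The 1612 other genes include 356 piRNA genes, 87.1% with a site, and genes that share a peak are not independent. Peaks without a full site may therefore carry part of some of these calls. That they carry the whole of a call was tested for each of the 6 lists over peaks with a site alone, with adjusted exact p over all 41 lists. It is argued against for homeodomain genes (ratio 3.10, 95% interval 1.72 to 5.60, adjusted exact p = 0.0159) and mitochondrial stress genes (ratio 8.37, 3.65 to 19.2, adjusted p = 0.0143). All 4 bound mitochondrial stress genes had a full site, so their result over these peaks followed from that count and is no separate test. The homeodomain list also passed over peaks without a site (ratio 5.72, adjusted exact p = 0.0140), with 10 of 15 bound members at a site, so such peaks are not ruled out as part of that call. For the other 4 lists the call ended, at adjusted exact p from 0.204 to 0.779, and the source cannot be told apart from the lower number of peaks. The cell cycle ratio was 2.65 (95% interval 1.47 to 4.76) over all peaks and 2.36 (1.16 to 4.82) over peaks with a site. The bZIP ratio was 3.83 (1.72 to 8.55) and 1.95 (0.509 to 7.44), the histone ratio 2.56 (1.38 to 4.75) and 1.44 (0.553 to 3.76), and the small nucleolar RNA ratio 2.44 (1.73 to 3.44) and 1.65 (1.02 to 2.68). In each case the second interval includes the first ratio. No biological explanation was tested.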
